A study of Homo sapiens
Mus musculus with 13 samples.

How the data were processed

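The samples were tumours grown from MDA-MB-231, a human triple-negative breast cancer cell line, in nude mice of the Balb/c strain (mammary fat pad), and each tumour held human tumour cells and mouse host cells. Per the labels, the 13 tumours fell into 4 groups: vehicle (3 tumours), docetaxel (3), a peptide inhibitor of protein kinase C theta, called PKCi here (3), and both drugs together, called combination here (4). Docetaxel, a taxane that stabilises microtubules, was given intraperitoneally at 4 mg/kg once a week for 3 weeks, and the inhibitor at 40 mg/kg each day for 5 weeks. Tumours were excised on day 50 after transplantation. Libraries came from a TruSeq mRNA kit and were read as pairs, per the labels' protocols. Each library is a tumour of its own per its label. p-values measure the spread between these tumours.

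The authors deposited raw read counts per gene, in a table of 58051 human identifiers and a table of 48795 mouse identifiers, with the same 13 libraries in both, since per the series' design text each library was mapped to both genomes. Per the submitters' processing notes, the tools were Trimmomatic 0.36, HISAT2 2.04, Picard, StringTie and edgeR, and the builds were hg38 and mm10. The versions of the other tools, the gene annotation, the strand setting and the handling of reads that map to both genomes are not given in the sources used here. Reads of conserved genes may therefore count in both tables, and overlapping genes and near-identical copies cannot be told apart. The counts were used as deposited, all columns were matched to a library by its label, and 0 columns were left unmapped.

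The deposited tables hold Ensembl identifiers and do not pair them with gene names. The reference table at hand lists 59792 human genes of GRCh38.p14 without Ensembl identifiers, so 0 of the identifiers in either table could be matched to a symbol. No gene name is therefore given, and at most 2 identifiers that rose and 2 that fell are printed per comparison. The 19 human and 26 mouse gene lists fixed before the data were examined (pathways, cell type markers), the values of the gene of the inhibited kinase, and the alternatives that needed symbols were not run.

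Human and mouse tables were analysed separately with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes with low counts were removed with filterByExpr, library sizes were scaled by TMM, dispersions were estimated robustly, and a quasi-likelihood F-test was run for 6 contrasts in a fit of all 13 libraries: each treatment against vehicle, the combination against each single drug, and the interaction, which is the change from docetaxel to combination minus the change from vehicle to PKCi. p-values were adjusted by the Benjamini-Hochberg method per contrast, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Group levels are in CPM of TMM-scaled libraries, as mean ± SD.

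The mouse share of a library is its mouse total divided by the sum of its mouse and human totals. Shares were compared between groups with exact two-sided permutation tests (scipy), which double the smaller tail, adjusted over 5 comparisons. In this test the smallest possible p is 0.1 with 3 tumours against 3 and 0.0571 with 3 against 4. Splits of the libraries in the gene tests were compared by their count of called genes, which has no direction, so each split was counted once and its share was not doubled. Intervals for single libraries are 95% Wilson intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

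The rule for naming genes was written before the data were examined. It takes the largest rises and falls among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups compared (the last condition not used for the interaction). It was applied without its condition on symbols and limited to 2 identifiers per direction. Where no gene met it, the 2 identifiers with the smallest p in each direction are given, although they did not pass. The parts of the rule that rest on gene lists could not be applied.

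The test was first run on simulated counts with the means, dispersions and library sizes of these tables and 200 changed genes. At a simulated 2-fold change in docetaxel against vehicle, 60% of changed genes were recovered in a run on 18247 human genes and 36% in a run on 15219 mouse genes. At 1.5-fold the shares were 22% in 18237 human genes and 0% in 15211 mouse genes. Recovery depends on the share of genes that change, and 200 genes are far fewer than the 17.7% of human genes called for docetaxel against vehicle. These rates need not hold for the real contrasts. Replicates were checked for duplicates by a chi-square test of their counts; the lowest value per degree of freedom was 24.4 in the human and 11.2 in the mouse table, so all libraries were counted as separate.

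Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, no filter on low counts, fits of only the groups compared, the replicate number as a block, the log2 ratio of mouse to human total as a covariate, and each library left out in turn. Thinning to the smallest library, and mouse shares without the 100 genes of highest total in each table, were added after seeing the data. Cell cycle phase lists were built from the gene pairs that scran 1.30.0 holds, with identifiers, for each phase. A narrow list took genes that came first in pairs of its phase, never second there and never first in another phase. A wider list took genes that came first more often than second by at least 10 pairs, and most so in its phase. Both were tested with fry and with camera with an estimated correlation, also chosen after seeing the data.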

Results

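The transcriptomes of 13 MDA-MB-231 tumours grown in nude mice were compared to describe how docetaxel, the PKC theta peptide inhibitor (PKCi) and their combination changed RNA of the tumour cells and of the host tissue around them. Human totals ranged from 30061554 to 43142059 counts per library and mouse totals from 4953782 to 10492268. After filtering, 18316 human and 15321 mouse genes were tested. The mouse table was both shallower and more variable, with a common biological coefficient of variation of 29% against 20.7% in the human table.

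The mouse share of counts was higher in each of the 10 treated tumours than in each of the 3 vehicle tumours. The mouse table took 12.4% ± 0.616 of all counts in vehicle tumours (SD, n = 3), 19.7% ± 1.65 in docetaxel tumours (n = 3), 17.5% ± 2.14 in PKCi tumours (n = 3) and 20.2% ± 2.73 in combination tumours (n = 4). The highest vehicle tumour stood at 13.1% and the lowest treated tumour, a PKCi tumour, at 15.1%. Counting error was small beside these differences, since the 95% Wilson interval of the vehicle 1 share ran from 12.07% to 12.09%. The difference from vehicle was 7.3 percentage points for docetaxel (exact permutation p = 0.1, adjusted 0.167), 5.1 points for PKCi (exact permutation p = 0.1, adjusted 0.167) and 7.8 points for the combination (exact permutation p = 0.0571, adjusted 0.167). Each of these p-values is the smallest that this two-sided test, which doubles the smaller tail, can give at its group sizes, so none could pass 0.05 in it. Combination and docetaxel tumours differed by 0.496 points (exact permutation p = 0.857, adjusted 0.857), and combination and PKCi tumours by 2.7 points (exact permutation p = 0.286, adjusted 0.357), both within the spread between tumours. The sign of the combination against docetaxel difference turned when combination 2, combination 3 or docetaxel 2 was left out, with differences of -0.324, -0.159 and -0.294 points.

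**Figure D1:**
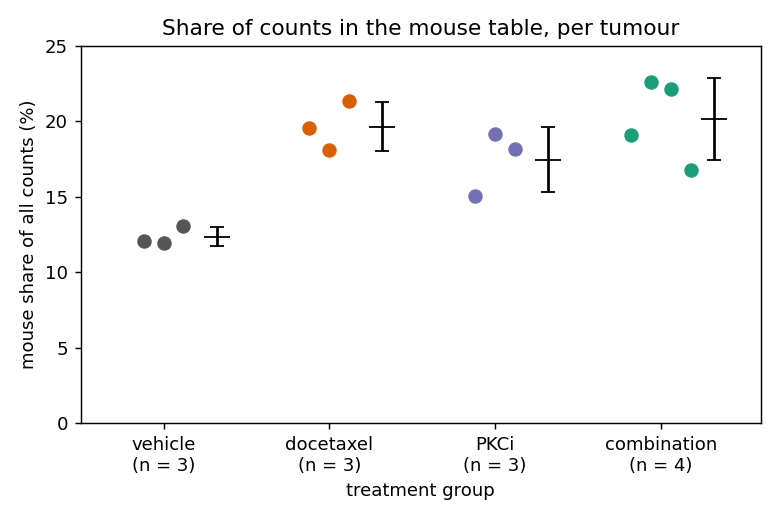
Share of all counts that lie in the mouse table (%, vertical axis) for each tumour (points) in the 4 treatment groups, with the group mean and SD as bars beside them. The 3 vehicle tumours lie between 11.9% and 13.1%, below all 10 treated tumours, which lie between 15.1% and 22.6%.

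Docetaxel alone gave the highest number of called human genes of the 6 contrasts. Against vehicle, 1746 human genes rose and 1498 fell, 17.7% of those tested. Most changes were modest: the median log2 fold change was 0.49 among genes that rose and -0.55 among genes that fell, and 198 rises and 352 falls exceeded 2-fold. ENSG00000136155 rose from 3.09 ± 2.1 to 47.9 ± 32.4 CPM (SD, n = 3 each; log2 fold change 3.96 ± 0.98 SE, edgeR adjusted p = 0.0205), and ENSG00000164283 rose from 12.4 ± 10.1 to 182 ± 57.8 CPM (3.87 ± 0.72 SE, adjusted p = 0.0058). ENSG00000163017 fell from 11.7 ± 8.55 to 1.03 ± 0.27 CPM (log2 fold change -3.51 ± 0.68 SE, adjusted p = 0.0066), and ENSG00000241489 from 10.2 ± 3.63 to 1.04 ± 0.244 CPM (-3.29 ± 0.73 SE, adjusted p = 0.0119). The first principal component of the human table, with 19.3% of the variance, set the 3 docetaxel tumours (30.3 to 61.9) apart from the other 10, none of which exceeded 3.7. The call of ENSG00000136155 was lost without vehicle 1, 2 or 3 or docetaxel 2 or 3 (adjusted p from 0.0502 to 0.0655), without a filter on low counts (0.051) and in a fit of these 2 groups alone (0.0518), and that of ENSG00000241489 without docetaxel 2 or 3 (0.0528). All 4 were lost with mouse content as a covariate (0.168 to 0.298), which took the count to 2, while the median log2 fold changes of the called genes were 0.53 and -0.55 and their median SE went from 0.111 to 0.218. The count fell to 1981 without docetaxel 2 and to 1973 without docetaxel 3.

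In the mouse table, 13 genes rose and 10 fell in docetaxel tumours against vehicle. Whether human reads counted in this table contributed was not tested. ENSMUSG00000069895 rose from 3.81 ± 0.589 to 66.1 ± 25.8 CPM (SD, n = 3 each; log2 fold change 4.11 ± 0.62 SE, edgeR adjusted p = 0.0444), and ENSMUSG00000047030 rose from 1.99 ± 0.471 to 25 ± 3.46 CPM (3.64 ± 0.23 SE, adjusted p = 3.4e-05). ENSMUSG00000102049 fell from 5.75 ± 0.828 to 0.774 ± 0.445 CPM (-2.85 ± 0.48 SE, adjusted p = 0.0492), and ENSMUSG00000105572 from 4.89 ± 1 to 1 ± 0.409 CPM (-2.27 ± 0.37 SE, adjusted p = 0.0492). Of these 4 identifiers, the call of ENSMUSG00000047030 held with each tumour left out, and those of the other 3 were lost whichever tumour was left out (adjusted p from 0.0722 to 0.185) and with mouse content as a covariate (0.464 to 0.777). An unadjusted p under 0.05 was found for 2336 mouse genes (15.2%), and DESeq2 called 559. With no effect at all, a share of about 0.05 of the genes tested would have such a p. The count fell below 7 when any of the 6 tumours compared was left out: to 1 without vehicle 1, vehicle 3 or docetaxel 1, to 2 without docetaxel 2, to 5 without docetaxel 3 and to 6 without vehicle 2. It was 1 with mouse content as a covariate, where the median log2 fold changes of the called genes went from 0.91 to 0.8 and from -1.02 to -1.3 and their median SE from 0.154 to 0.302. It was 13 without a filter on low counts and 12 in a fit of these 2 groups alone.

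No human gene passed the threshold for the inhibitor alone against vehicle in edgeR. The smallest adjusted p was 0.189, with 1748 genes (9.54%) at an unadjusted p under 0.05 and 115 genes called by DESeq2. The identifiers with the smallest p did not pass: ENSG00000182809 stood at 56.9 ± 1.21 CPM in vehicle and 91.7 ± 14 in PKCi tumours (n = 3 each), ENSG00000122863 at 67.1 ± 5.23 and 97.8 ± 9.48, ENSG00000172738 at 3.37 ± 0.219 and 1.77 ± 0.0513, and ENSG00000115464 at 217 ± 13 and 163 ± 17.8. Up to 9 genes were called when a tumour was left out: 9 without PKCi 2, 2 without vehicle 1, and 1 without vehicle 3 or PKCi 3.

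For the inhibitor alone against vehicle, 2 mouse genes were called. ENSMUSG00000047030 rose from 1.99 ± 0.471 to 21.8 ± 3.78 CPM (SD, n = 3 each; log2 fold change 3.44 ± 0.23 SE, edgeR adjusted p = 6.54e-05). ENSMUSG00000052534 fell from 44.3 ± 2.08 to 13.1 ± 0.951 CPM (-1.76 ± 0.19 SE, adjusted p = 0.0046), and all 3 PKCi tumours lay between 12.4 and 14.2 CPM. Its levels in docetaxel and combination tumours were 46.2 ± 9.46 (n = 3) and 46.3 ± 9.43 CPM (n = 4). The call of ENSMUSG00000052534 was lost with mouse content as a covariate (log2 fold change -1.51, adjusted p = 0.505) and narrowly without PKCi 2 (0.0594) or PKCi 3 (0.0527). The count of called genes was 4 without vehicle 2, 1 without PKCi 2 or PKCi 3, and 9 in a fit of these 2 groups alone; DESeq2 called 114.

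**Figure D2:**
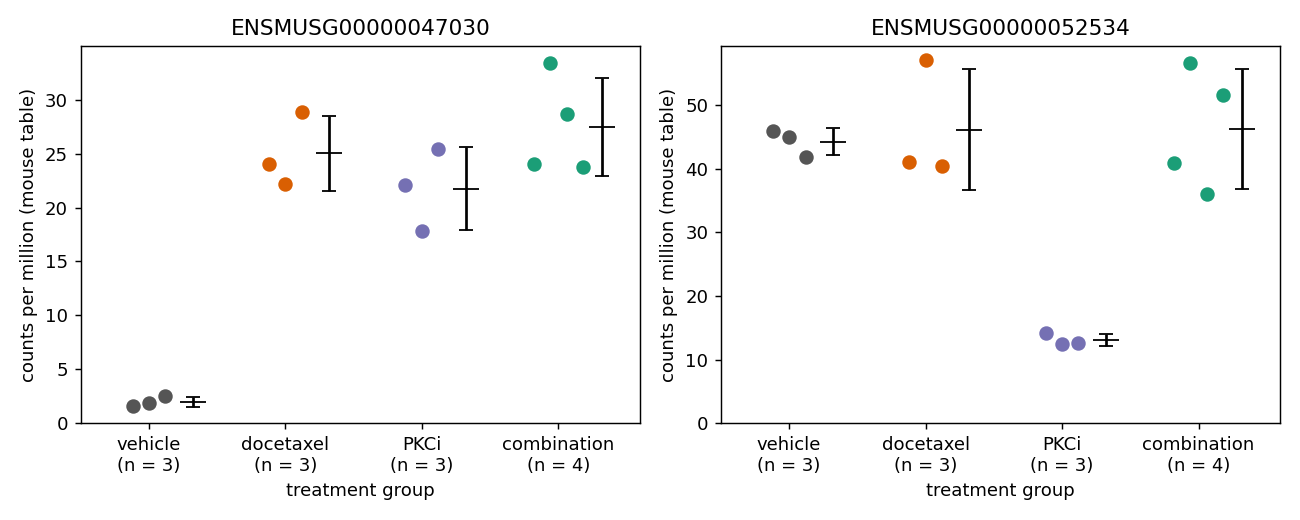
Level of 2 mouse genes (CPM in the mouse table, vertical axes) in each tumour (points) by treatment group, with the mean and SD as bars. ENSMUSG00000047030 is at 1.59 to 2.51 in the vehicle tumours and at 17.8 to 33.4 in the treated ones, and ENSMUSG00000052534 is at 12.4 to 14.2 in the PKCi tumours and at 36.1 to 57.1 in the others.

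The combination changed human genes in both directions against vehicle: 1212 rose and 918 fell, 11.6% of those tested. The median log2 fold change was 0.44 among rises and -0.44 among falls, and 52 rises and 112 falls exceeded 2-fold. ENSG00000182648 rose from 2.44 ± 0.339 (n = 3) to 11.7 ± 0.88 CPM (n = 4; log2 fold change 2.27 ± 0.43 SE, edgeR adjusted p = 0.00871), and ENSG00000204054 from 5.65 ± 1.3 to 18.4 ± 0.52 CPM (1.71 ± 0.25 SE, adjusted p = 0.00352). ENSG00000240602 fell from 11.2 ± 5.86 to 1.38 ± 0.71 CPM (-3.02 ± 0.66 SE, adjusted p = 0.0176), and ENSG00000274391 from 4.9 ± 3.08 to 0.696 ± 0.426 CPM (-2.8 ± 0.7 SE, adjusted p = 0.0279). The call of ENSG00000240602 was lost without vehicle 1 (adjusted p = 0.0756), and that of ENSG00000274391 without vehicle 1 or 2 or combination 1, 3 or 4 (0.0505 to 0.113) and without a filter on low counts (0.0773). The count was 599 without vehicle 1, 1059 without vehicle 3, and 1416, 1399, 1378 and 1122 without combination 1, 2, 3 and 4. With mouse content as a covariate it was 0, these 4 identifiers included (adjusted p from 0.247 to 0.697), at median log2 fold changes of 0.49 and -0.46 and a median SE that went from 0.099 to 0.212.

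Of the contrasts in the mouse table, combination against vehicle gave the most called genes, with 192 genes higher and 143 lower than in vehicle tumours. The median log2 fold change was 0.65 among rises and -0.56 among falls, and 38 rises and 25 falls exceeded 2-fold. ENSMUSG00000069895 rose from 3.81 ± 0.589 (n = 3) to 57.4 ± 37.8 CPM (n = 4; log2 fold change 3.91 ± 0.6 SE, edgeR adjusted p = 0.0195), and ENSMUSG00000047030 from 1.99 ± 0.471 to 27.4 ± 4.57 CPM (3.77 ± 0.23 SE, adjusted p = 1.7e-05). ENSMUSG00000091971 fell from 67.9 ± 9.29 to 14.5 ± 5.96 CPM (-2.22 ± 0.42 SE, adjusted p = 0.0315), and ENSMUSG00000014543 from 6.47 ± 0.624 to 1.41 ± 0.92 CPM (-2.2 ± 0.49 SE, adjusted p = 0.0444). The call of ENSMUSG00000047030 held with each tumour left out. That of ENSMUSG00000069895 was lost without vehicle 1, 2 or 3 or combination 4 (adjusted p from 0.051 to 0.0828), that of ENSMUSG00000091971 whichever tumour was left out (0.0509 to 0.119), and that of ENSMUSG00000014543 without any 1 tumour except combination 3 (0.0769 to 0.126); all 3 were lost with mouse content as a covariate (0.194 to 0.678). The count depended on each tumour: it was 8, 21 and 3 without vehicle 1, 2 and 3, and 154, 68, 108 and 31 without combination 1, 2, 3 and 4. It was 1 with mouse content as a covariate, where the median log2 fold changes of the called genes went from 0.65 to 0.6 and from -0.56 to -0.45 and their median SE from 0.122 to 0.254. It was 197 without a filter on low counts and 193 in a fit of these 2 groups alone, and DESeq2 called 1129.

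**Figure D3:**
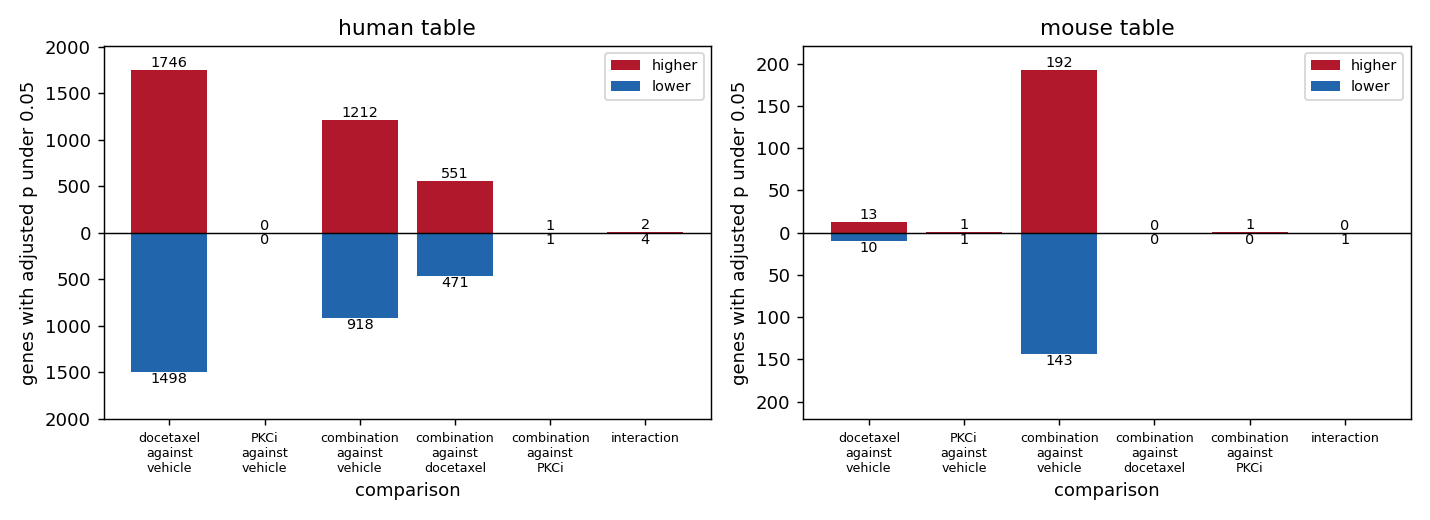
Number of genes called higher (upward bars) or lower (downward bars) at an edgeR adjusted p under 0.05 in each of the 6 contrasts, in the human table (left) and the mouse table (right), whose vertical axes differ. Docetaxel against vehicle has the tallest human bars (1746 and 1498) and combination against vehicle the tallest mouse bars (192 and 143).

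The effect of adding the inhibitor to docetaxel was read from combination against docetaxel tumours. In the tumour cells 551 human genes were higher and 471 lower in the combination. The median log2 fold change was 0.78 among the higher and -0.56 among the lower genes, and 216 and 103 of them exceeded 2-fold. ENSG00000241489 was at 18.6 ± 13.7 CPM in the combination (n = 4) against 1.04 ± 0.244 with docetaxel (n = 3; log2 fold change 4.15 ± 0.73 SE, edgeR adjusted p = 0.0142), and ENSG00000163017 at 17.6 ± 6.47 against 1.03 ± 0.27 CPM (4.1 ± 0.68 SE, adjusted p = 0.0122). Both had fallen in docetaxel against vehicle, which uses the same docetaxel tumours, so low values in these favour both changes. ENSG00000283460 was lower in the combination, at 0.604 ± 0.366 against 6.16 ± 4.49 CPM (-3.35 ± 0.73 SE, adjusted p = 0.0281), as was ENSG00000181577, at 1.24 ± 0.548 against 9.42 ± 8.66 CPM (-2.94 ± 0.61 SE, adjusted p = 0.0226). The calls of the first 2 identifiers were lost without docetaxel 2 or 3 (adjusted p from 0.0573 to 0.0738), that of ENSG00000283460 without docetaxel 1 or 2 or combination 2, 3 or 4 (0.0519 to 0.107) and that of ENSG00000181577 without docetaxel 2 or combination 1, 2 or 4 (0.0548 to 0.0826). DESeq2 called 1880 genes. The count was 200 without docetaxel 2, 223 without docetaxel 3, and 374, 293 and 653 without combination 1, 2 and 4.

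No mouse gene passed between combination and docetaxel tumours in edgeR, where the smallest adjusted p was 0.336. An unadjusted p under 0.05 was found for 967 genes (6.31%), a share near the 0.05 that no effect would give. DESeq2 called 75. Of the identifiers with the smallest p, none of which passed, ENSMUSG00000044350 stood at 109 ± 26.2 CPM in combination (n = 4) and 42.6 ± 6.11 in docetaxel tumours (n = 3), ENSMUSG00000063849 at 48.9 ± 4.78 and 32.2 ± 2.6, ENSMUSG00000029377 at 6.25 ± 0.556 and 13.9 ± 3.73, and ENSMUSG00000020592 at 236 ± 12.5 and 340 ± 45. Without docetaxel 2 or docetaxel 3, 1 gene was called.

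The effect of adding docetaxel to the inhibitor was read from combination against PKCi tumours, where 1 human gene rose and 1 fell. ENSG00000182095 rose from 103 ± 7.9 (n = 3) to 159 ± 9.79 CPM (n = 4; log2 fold change 0.63 ± 0.07 SE, edgeR adjusted p = 0.00964). ENSG00000085982 fell from 74.7 ± 2.98 to 47.4 ± 1.12 CPM (-0.66 ± 0.06 SE, adjusted p = 0.00166). At an unadjusted p under 0.05 there were 2862 human genes (15.6%), and DESeq2 called 722. In a fit of these 2 groups alone ENSG00000182095 was not called (adjusted p = 0.0543). The edgeR count rested on PKCi 3, without which it was 638; it was 5 without PKCi 1, PKCi 2 or combination 2, 31 without a filter on low counts and 8 in a fit of these 2 groups alone.

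Of the mouse genes, 1 passed between combination and PKCi tumours. ENSMUSG00000052534 was at 46.3 ± 9.43 CPM in the combination (n = 4) against 13.1 ± 0.951 with PKCi (n = 3; log2 fold change 1.83 ± 0.18 SE, edgeR adjusted p = 0.00372). Its fall in PKCi against vehicle used the same PKCi tumours, so low values in these favour both changes. A trait of the PKCi tumours alone cannot be told apart from a drug effect, and the interaction of this gene was not called. There were 1101 genes (7.19%) at an unadjusted p under 0.05, and DESeq2 called 30. The count was 13 without PKCi 3, 3 without PKCi 1 and 0 without PKCi 2 (adjusted p of ENSMUSG00000052534 = 0.0595) and in a fit of these 2 groups alone (0.0656).

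The interaction asked whether the inhibitor's effect differed with and without docetaxel. Of the human genes, 2 had a higher and 4 a lower inhibitor effect in the presence of docetaxel. ENSG00000111199 was at 1.68 ± 0.655 CPM in vehicle, 0.392 ± 0.0538 in docetaxel, 2.1 ± 0.197 in PKCi and 3.42 ± 0.62 in combination tumours (interaction 2.8 ± 0.41 SE on the log2 scale, edgeR adjusted p = 0.045). ENSG00000130649 stood in the same order of groups at 7.46 ± 1.29, 2.41 ± 0.597, 5.98 ± 0.899 and 7.85 ± 1.41 CPM (2.02 ± 0.3 SE, adjusted p = 0.045). ENSG00000128591 was at 62.4 ± 4.05, 201 ± 10.5, 74.5 ± 6.41 and 110 ± 17.8 CPM (-1.13 ± 0.16 SE, adjusted p = 0.045), and ENSG00000104998 at 19.3 ± 0.611, 44.7 ± 3.11, 23.7 ± 3.55 and 26 ± 3.03 CPM (-1.08 ± 0.16 SE, adjusted p = 0.045). These calls lay at the threshold: the count was 0 without vehicle 2, vehicle 3, docetaxel 3, PKCi 1, combination 1 or combination 4, 1 to 3 without docetaxel 2, PKCi 2 or combination 2, and 27, 23 and 13 without vehicle 1, PKCi 3 and combination 3. It was also 0 with mouse content as a covariate and in thinned libraries, 48 without a filter on low counts, and 678 in DESeq2. With the covariate, the median interaction of the called genes went from 2.41 to 2.63 and from -0.95 to -0.86. Their median SE went from 0.162 to 0.213.

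In the mouse table the interaction passed for 1 gene. ENSMUSG00000047030 was higher with each single drug than in vehicle and showed no called difference between the combination and either single drug. It was at 1.99 ± 0.471 CPM in vehicle (n = 3), 25 ± 3.46 in docetaxel (n = 3), 21.8 ± 3.78 in PKCi (n = 3) and 27.4 ± 4.57 in combination tumours (n = 4). The interaction was -3.31 ± 0.29 SE (edgeR adjusted p = 0.00115). Its call held in every alternative fit and with each tumour left out, with values from -2.98 to -3.5. The vehicle levels rest on 8, 11 and 14 counts. A trait of the vehicle tumours alone cannot be told apart from a rise under each drug. DESeq2 called 15 mouse genes, and the edgeR count reached 2 or 3 without vehicle 2, docetaxel 2, docetaxel 3, PKCi 1, or combination 1, 2 or 3.

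The response to docetaxel with and without the inhibitor was compared in libraries that the comparisons do not share. Of the 3244 human genes called in docetaxel against vehicle, 2715 (83.7%) had the same direction in combination against PKCi. Their median change in the direction of the docetaxel response was 0.17 on the log2 scale there, against 0.51 in docetaxel against vehicle. Of the 1022 genes called in combination against docetaxel, 59.7% had the same direction in PKCi against vehicle, with a median of 0.06 against 0.68. The values 0.51 and 0.68 were measured in the libraries that selected the genes, which may inflate them.

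**Figure D4:**
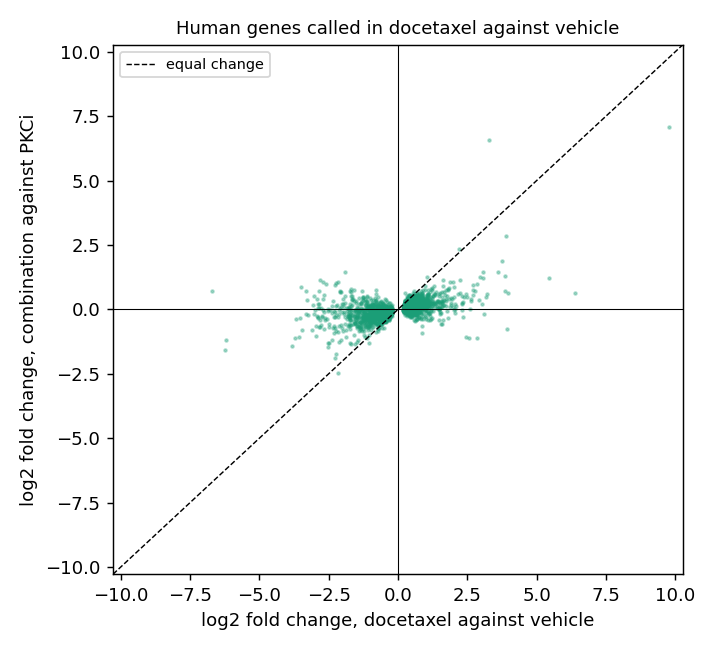
Log2 fold change of each of the 3244 human genes called in docetaxel against vehicle (horizontal axis), against its log2 fold change in combination against PKCi (vertical axis), which shares no library with it; the dashed line marks equal change. Most points (83.7%) share their sign, and their median change is 0.17 on the vertical against 0.51 on the horizontal axis.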

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

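The interaction test was fixed before the data were examined, and the search for distant libraries followed a fixed criterion. The interaction term of the edgeR model was called for 6 human genes and 1 mouse gene, and 4 of the human identifiers are printed here. In the human table the interaction was 2.8 for ENSG00000111199, 2.02 for ENSG00000130649, -1.13 for ENSG00000128591 and -1.08 for ENSG00000104998, on the log2 scale, each at an adjusted p of 0.045. In each of these 4 genes the docetaxel mean stood apart from vehicle and the combination mean lay nearer to PKCi than the docetaxel mean did. The adjusted p of these genes rose above 0.05 with mouse content as a covariate and in thinned libraries. With the covariate, the median interaction of the 6 called genes stayed about as large (2.41 to 2.63 and -0.95 to -0.86). The human count also fell to 0 without combination 1 and without some other single tumours. In the mouse table the interaction was -3.31 for ENSMUSG00000047030, because the gene was at 21.8 to 27.4 CPM on average in every treated group and at 1.99 CPM in vehicle.

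In the combination group, combination 2 lay far from the other 3 tumours in 2 of the 34 quantities examined. Its mouse total was 10492268 counts against 8539897 to 8716646, and ENSG00000182809 stood at 102 CPM in it against 90.4 to 92.2. Chance alone gives such a gap in about 1 of 20 groups.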

How the results depend on the processing

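Thinning to the smallest library and leaving out the 100 highest-count genes were chosen after seeing the data. The cause of a moved count was not tested, except where a value or the construction of the alternative shows it. RLE scaling kept each count within 1.5 times except the mouse interaction (2). DESeq2, another test, gave 115 human genes for PKCi against vehicle, 1880 for combination against docetaxel, 722 for combination against PKCi and 678 for the interaction, and for mouse genes the counts were 559, 114, 1129, 75, 30 and 15 in the order of the report's contrasts (docetaxel, PKCi and combination against vehicle, combination against docetaxel and against PKCi, interaction). Without a filter there were 31 human genes for combination against PKCi and 48 for the interaction, and 13, 197 and 3 mouse genes for docetaxel and combination against vehicle and the interaction. Fits of only 2 groups, with fewer samples, gave 8 human genes for combination against PKCi, and 12, 9, 193 and 0 mouse genes for docetaxel, PKCi and combination against vehicle and combination against PKCi. Thinning gave 0 human and 3 mouse genes for the interaction.

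With mouse content as a covariate, 2, 0 and 0 human genes were called for docetaxel and combination against vehicle and for the interaction, and 1 mouse gene each for docetaxel, PKCi and combination against vehicle. Every treated tumour lay above every vehicle tumour in mouse content, so the covariate overlaps with the contrasts against vehicle, and the SE about doubled (0.111 to 0.218 in called human docetaxel genes) while the median log2 fold change of the rises went from 0.49 to 0.53.

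With the replicate number as a block, the human counts were 685 for combination against vehicle, 235 for combination against docetaxel, and 0 for combination against PKCi and for the interaction, and the mouse counts were 1 for docetaxel and 85 for combination against vehicle; the other counts stayed within 1.5 times. In the human table the numbers showed no pairing of the tumours. Deviations of same-numbered tumours correlated at -0.074 to 0.069, over 0.1 in 0 of 18 pairs, and 3 of 12 tumours correlated best with their own number. In the mouse table the correlations ran from -0.32 to 0.43 (mean 0.014), over 0.1 in 6 of 18 pairs. There 6 of 12 tumours correlated best with their own number, so these values do not settle whether the numbers pair the tumours.

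With 1 tumour left out, human counts ranged from 1973 to 2603 (docetaxel against vehicle), 0 to 9 (PKCi against vehicle), 599 to 1850 (combination against vehicle), 200 to 808 (combination against docetaxel), 2 to 638 (combination against PKCi) and 0 to 27 (interaction). Mouse counts ranged from 1 to 6, 1 to 4, 3 to 154, 0 to 1, 0 to 13 and 1 to 3 in the same order. The mouse share difference of combination against docetaxel ranged from -0.324 to 1.61 points and was below 0 without combination 2 (-0.324), combination 3 (-0.159) or docetaxel 2 (-0.294). The other 4 share differences kept their sign, and none of the 5 could reach an exact p under 0.05 at these group sizes.

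No log2 fold change of a named identifier turned its sign under any alternative that gave one. Of the 540 such values, 372 stayed on their side of the threshold, 158 lost the call and 10 gained it. The lower depth and the larger spread of the mouse table, which were not separated, limit it more: in simulated docetaxel against vehicle data, 36% of 2-fold changes were recovered there (15219 genes) against 60% in the human table (18247 genes). The alternative that leaves out genes with a more abundant counterpart in the other species, and the mouse shares without mitochondrially encoded genes or without genes with a counterpart of the same symbol, were not run, because they need gene symbols.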

Other observations

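All tests in this part were chosen, with their thresholds, after the results they weigh had been seen. Cell cycle marker lists built from the scran gene pairs were read in both tables, 18 tests per table and definition of the lists. Over all human genes tested, 17.7% were called in docetaxel against vehicle and 11.6% in combination against vehicle. Of 43 measured human markers of the G2 and M phases alone, 11 rose and 3 fell under docetaxel against vehicle. Their median log2 fold change was 0.11 (fry adjusted p = 0.0273, camera adjusted p = 0.692 with an estimated correlation). In combination against vehicle, 5 of these markers rose and 1 fell, with a median of 0.11 (fry adjusted p = 0.0273; camera adjusted p = 0.61 with an estimated correlation). In combination against PKCi none of them was called, and the list moved up by a median of 0.13 (fry adjusted p = 0.0273; camera adjusted p = 0.432 with an estimated correlation), as did 29 markers of the S phase, by 0.12 (fry adjusted p = 0.0273; camera adjusted p = 0.432 with an estimated correlation). All 4 of these calls by fry were thus lost in camera, which compares a list with the other genes. A wider list of 286 G2 and M phase markers under docetaxel against vehicle had 29 rises and 46 falls, with a median of -0.05 (fry adjusted p = 0.444), and none of the wider human lists passed in any of the 6 contrasts. A hypothesis that more tumour cells were in G2 or M phase may account for the narrow list (fry adjusted p = 0.0273). The wider definition gave a median of the other sign and no call. Genes of the wider list can also come second in pairs of the phase. Both lists rest only on the order within pairs, so genes of either need not mark the phase. The hypothesis stays open. In the mouse table, markers of the G1 phase fell on balance under the combination against vehicle in both definitions, with a median of -0.25 over 9 genes (fry adjusted p = 0.0184, camera adjusted p = 0.253 with an estimated correlation) and -0.13 over 200 genes (fry adjusted p = 0.00675, camera adjusted p = 0.171 with an estimated correlation), so both calls were lost in camera. Over all genes tested 0 of the 9 and 7 of the 200 fell, and 4 and 13 were called when adjusted over the list alone. Of all mouse genes tested, 2.19% were called in this contrast.

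The mouse share was higher in all 10 treated tumours (19.2% on average) than in the 3 vehicle tumours (12.4%). Assignment by chance is argued against by an exact two-sided permutation test of these 13 tumours (p = 0.00699, the smallest that this test can give for them), although the treated groups were pooled after their values were seen. A few abundant genes are argued against too, since the difference was 6.84 percentage points with all genes and 6.69 points without the 100 highest-count genes of each table. Smaller tumours, host cells entering after treatment and dissection remain open and were not tested, since tumour sizes and histology were not analysed here.

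Mouse reads counted in the human table could raise human genes in docetaxel tumours, whose mouse to human ratio was 0.79 higher on the log2 scale than in vehicle tumours. To give the median rise of 0.49, these genes would need a slope of 0.62 on that ratio; within groups the median slope of the 1746 genes was -0.05 (-0.1 to 0.01 with each library left out). For the 1498 falls, a slope of -0.69 would be needed and the median was 0.02 (-0.04 to 0.06). PKCi tumours, with a ratio 0.58 higher than vehicle, showed a median change of only 0.07 to 0.13 in the docetaxel direction for genes selected without the vehicle tumour used. Mouse reads as the cause of all these changes are therefore argued against, single genes stay open, and a drug response of the tumour cells is a hypothesis. The reverse, human reads counted in the mouse table, was not tested, so changes there need not all come from host tissue.

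For genes called in docetaxel against vehicle, the median docetaxel response was smaller beside the inhibitor. Selection of genes for a large change in the docetaxel tumours may inflate it, so genes were selected in 9 fits that each held out 1 docetaxel and 1 vehicle tumour. In the held-out pair the median effect was 0.44 to 0.55. This lay above the highest of the 12 single pairs of combination against PKCi (0.27) in 9 of 9 fits. These values argue against noise of the selecting tumours as the whole cause. The 9 fits share tumours and are not independent. All of them selected genes in docetaxel against vehicle, so genes that respond more without the inhibitor may still be favoured. Selection of genes in combination against PKCi was not run. Mouse content goes with the pattern in part, since its log2 shift was 0.79 for docetaxel against vehicle and 0.25 for combination against PKCi, but the combination reached only 0.25 to 0.32 against the held-out vehicle tumour at a shift of 0.83. Compared directly, the held-out docetaxel tumour exceeded the combination mean by a median of only 0.13 to 0.26, at a group shift of 0.04. The PKCi mean itself lay 0.07 to 0.13 from the held-out vehicle tumour in the docetaxel direction, so part of the gap lies in that baseline. A weaker response to docetaxel beside the inhibitor remains a hypothesis, found and tested on the same tumours. Differences in tumour size or in dose reaching the tumours were not tested.

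Other splits of the same libraries were tested with the same model. For docetaxel against vehicle and PKCi against vehicle the 10 splits are too few for a share under 0.05; the real and highest other counts were 3244 and 1 (1 split as large) and 0 and 2 (10 splits as large) in the human table, and 23 and 1 (1 split) and 2 and 0 (1 split) in the mouse table. Where the real count is 0, as for human PKCi against vehicle and for mouse combination against docetaxel (highest other 41, 35 of 35), every split is as large and the count tests nothing. For combination against vehicle, 1 of 35 splits, the real one, gave as many genes in the human table (2130, highest other 2). The same held in the mouse table (192 higher and 143 lower, highest other 3 in all). It also held for the human genes of combination against docetaxel (1022, highest other 4, 1 of 35). A share of 1 of 35 is the smallest possible at these group sizes and was not adjusted over the contrasts. It argues against chance in these cases but does not exclude it. By the count of calls, chance stays open for combination against PKCi, both for human genes (2, highest other 2, 3 of 35) and for mouse genes (1, highest other 158, 7 of 35). For the interaction, redrawn groups mix the effects of the single drugs into the spread, so the splits decide nothing about it: the human count was 6 (highest other 3, 1 of 100 drawn) and the mouse count 1 (highest other 172, 14 of 100 drawn). The split with 158 genes set PKCi 1, PKCi 2, combination 3 and combination 4 against the other 3. It was the highest of the 35 splits, and whether a trait of the host tissue or of the handling sets these 4 tumours apart was not tested. In the same counts, these 4 tumours had the lowest values on the first principal component of the mouse table (-36.3 to -46.9, 23.6% of the variance).

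The median aligned change of 0.17 for docetaxel genes in combination against PKCi was reached by 1 of 35 splits of those libraries (highest other 0.13), whereas the 0.06 for combination against docetaxel genes in PKCi against vehicle was reached by 6 of 20. The share of 1 of 35 is the smallest possible there. For the docetaxel genes as a set, it argues against chance in combination against PKCi but does not exclude it. For the 6 of 20, chance stays open.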
